A study of Mus musculus with 6 samples.

How the data were processed

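The data are RNA sequencing libraries of mouse spinal cord microglia, 3 from non-transgenic (NTg) mice and 3 from ATXN2-Q33;TDP-43 double mutants, each from a pool of 3 spinal cords of animals aged 7 months. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a stranded kit for low input. The deposited table holds raw fragment counts per gene, per the file headers, which record featureCounts 1.6.1 with paired fragments counted once, chimeric pairs left out, strand setting 2 and GENCODE release vM25; a fragment that overlaps several genes was counted for each of them. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.1, checked with FastQC and aligned with TopHat2 to mm10, and DESeq2 was used. Because the counting used strand, antisense genes are separate; reads shared between genes on the same strand count more than once, and none of the 13 named genes had an exon overlap with another gene on its strand. The recorded options count no read with several alignments, so members of families with near-identical copies are under-counted. The table also holds 6 columns of other samples, which were not used.

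Counts were used as deposited. Gene symbols were taken by Ensembl identifier from an annotation table of the same assembly: 55141 of 55401 genes matched and 260 did not. Coordinates are those of the deposited table on mm10. Library totals ran from 12553570 to 22854628 counts. The most abundant gene, Gm23935, took 6.01% to 8.08% of the counts of a library, and mitochondrial genes took 4.67% to 5.71%. Library pairs were compared by a chi-square test of their counts: the statistic per degree of freedom was 6.10 to 33.6, so no pair agreed within sampling noise and each library counted as 1 replicate.

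Genes were filtered with filterByExpr (minimum count 10), which left 16248, and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, a robust quasi-likelihood fit and the contrast ATXN2-Q33;TDP-43 minus NTg without covariates, with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. The common biological coefficient of variation was 0.261. Standard errors were taken from the unshrunk fold change and the F statistic, and 95% intervals from the t distribution with the test's degrees of freedom. CPM values use the TMM-scaled library sizes. Exact two-sided permutation tests used log2 CPM with a pseudocount of 0.5, and the smallest p for 3 against 3 libraries is 0.1. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives; DESeq2 gave no adjusted p for 15 genes.

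For gene groups, 43 lists of pathways, microglial states and cell types were fixed, of which 42 had at least 5 tested members. The list of Schwann cell markers had 4 of 10 members tested and was not analysed as a set; its summed counts ran from 5340 to 10006 per library, nearly all from Pmp22 and Egr2. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Of the listed symbols, 3 were not matched or repeat another name of the same gene.

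The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes Tardbp and Atxn2, then the 10 largest changes in each direction past the threshold at a mean of at least 1 CPM without overlap between groups; where fewer than 5 pass, the genes with the smallest p are added up to 5 and given as values. Gene models without a proper symbol and pseudogenes are counted but not named unless fewer than 5 others pass. For each list described, the rule names up to 4 members past the threshold, or otherwise the 2 or 3 with the smallest p. In the Results some lists are given with fewer members than that, or with none. Clec7a is typed as a polymorphic pseudogene in the annotation, so the first part of the rule passes it over although its p is the second smallest; it is named as the first member of its list, a point settled after its values were seen. P2ry12, Tmem119, Cx3cr1, S100a9, Gm42653 and Emp1 were also named after their values were seen.

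The edgeR and camera steps were tested on simulated counts drawn with the real means, library sizes and dispersions (15880 genes after the filter). Each gene was drawn independently, so structure shared by the genes of a library was not simulated. Of genes changed 1.5-fold, 2-fold and 4-fold, 12.3%, 39.7% and 62.5% were called; above 10 CPM these shares were 25.0%, 74.2% and 96.9%. Of 82 calls, 8 were unchanged genes. Alternatives covered the normalization, the test, the filter, the genes in the library size, the threshold, a residual principal component and leaving out each library. Added after the data were seen were a block of neighbouring sample codes, the ratio of Y-linked genes to Xist, the combined alignments as a covariate or left out, and leaving out NTg replicate 9 with ATXN2-Q33;TDP-43 replicate 10. Of the follow-up tests in the closing section, 3 were revised after a first form had given a result. A first test for strain-specific DNA on chromosome 6 used the same low p-values that defined the stretch, was judged circular and was replaced by the test of the other genes there. The ratio of ependymal to oligodendrocyte markers was first read as decisive and was repeated without Trf, which changed that reading. The test of carried-over cells on chromosome 6 first asked only for the share of the fold kept, was then also held to the members' p-values, and last to the count of genes in the 10 Mb bin; the last 2 forms left it open.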

Results

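RNA was sequenced from microglia, the resident macrophages of the central nervous system, taken from the spinal cords of 7-month-old mice with beads coated against CD11b, a surface integrin of myeloid cells. The 2 groups were non-transgenic mice (NTg, C57BL/6) and heterozygous double mutants (ATXN2-Q33;TDP-43), which carry a knock-in of human ATXN2 with 33 glutamines together with human TDP-43. Both proteins bind RNA and are linked to amyotrophic lateral sclerosis. Each library came from a pool of 3 spinal cords and each group had 3 libraries from 9 animals, so the replicates are separate pools of animals. They are named here by the number in the sample titles: NTg replicates 7, 9 and 11, and ATXN2-Q33;TDP-43 replicates 8, 10 and 12. Total counts per library ran from 12553570 in NTg replicate 7 to 22854628 in NTg replicate 11, and 16248 of 55401 genes had enough counts to be tested. The comparison asks whether the RNA of spinal cord microglia differs between the genotypes.

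The 2 genes of the genotype were read first. Tardbp, the mouse gene of TDP-43 (ENSMUSG00000041459, mm10 chromosome 4, 148612382 to 148627019), stood at 95.0 ± 1.55 CPM in NTg and 98.4 ± 8.52 CPM in ATXN2-Q33;TDP-43 libraries (SD, n = 3 each). Its log2 fold change was 0.05 (SE 0.09, 95% interval -0.15 to 0.25; exact two-sided permutation p = 0.6). Single libraries gave 93.3, 96.4 and 95.4 CPM in NTg replicates 7, 9 and 11 and 88.6, 103 and 104 CPM in ATXN2-Q33;TDP-43 replicates 8, 10 and 12. Atxn2 (ENSMUSG00000042605, mm10 chromosome 5, 121711337 to 121816493) measured 95.4 ± 1.06 and 101.6 ± 2.41 CPM (SD, n = 3 each). Its log2 fold change was 0.09 (SE 0.08, 95% interval -0.08 to 0.26). The Atxn2 values were 94.1, 96.0 and 95.9 CPM in NTg and 104, 99.5 and 101 CPM in the mutants, without overlap, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries allow. Reads from the human sequences can align to the mouse genes only in part, and no human sequence was counted. Both intervals include 0, so these values neither verify nor contradict the genotype labels.

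In the fit without a block no gene passed the threshold between the genotypes, and the genes with the smallest p-values are given here as values. Plxnd1, a receptor for semaphorins (ENSMUSG00000030123, mm10 chromosome 6, 115954811 to 115995005), measured 13.7 ± 2.93 CPM in NTg and 42.3 ± 7.21 CPM in ATXN2-Q33;TDP-43 libraries (SD, n = 3 each), a log2 fold change of 1.62 (SE 0.18, 95% interval 1.21 to 2.04, edgeR adjusted p = 0.113). Hebp1, which codes for a heme-binding protein (mm10 chromosome 6, 135137522 to 135198022), measured 19.4 ± 0.95 and 33.4 ± 5.01 CPM, a log2 fold change of 0.79 (SE 0.13). Cd209c, a C-type lectin of the DC-SIGN family (mm10 chromosome 8, 3940222 to 3954746), had 2, 4 and 8 counts in the NTg libraries and 30, 30 and 51 in the mutants, a log2 fold change of 3.05 (SE 0.49). Its family holds several near-identical copies, so its level is uncertain. Cfap99, named for cilia and flagella, and Sgsm1, a modulator of small GTPases, had log2 fold changes of 2.39 (SE 0.57) and 2.05 (SE 0.51) at 1.61 and 3.03 CPM in the mutants.

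On the negative side, Plau, which codes for the urokinase plasminogen activator (mm10 chromosome 14, 20836660 to 20843385), measured 423.5 ± 17.1 CPM in NTg and 315.1 ± 9.55 CPM in ATXN2-Q33;TDP-43 libraries (SD, n = 3 each), a log2 fold change of -0.43 (SE 0.08). Vcam1, a cell adhesion molecule, measured 106 ± 5.10 and 78.2 ± 4.87 CPM, a log2 fold change of -0.43 (SE 0.09). Atp6v1e1, a subunit of the proton pump that acidifies lysosomes, measured 102 ± 6.17 and 75.5 ± 5.98 CPM, a log2 fold change of -0.44 (SE 0.09). Olfr111, of the olfactory receptor family, which holds near-identical copies, and Tubb1, a beta tubulin known from platelets, had log2 fold changes of -0.90 (SE 0.18) and -1.17 (SE 0.25). Clec7a, the beta-glucan receptor Dectin-1 and a member of the disease-associated microglia list (ENSMUSG00000079293, mm10 chromosome 6, 129461591 to 129472779), measured 172 ± 13.3 CPM in NTg and 96.9 ± 7.95 CPM in the mutants. Its log2 fold change was -0.83 (SE 0.10, 95% interval -1.05 to -0.61, edgeR adjusted p = 0.113). For each of these 11 genes the libraries of the 2 groups did not overlap, with an exact two-sided permutation p of 0.1, the smallest this design allows. The genes were picked by their p-values, so the separation is not independent of that choice.

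**Figure D1:**
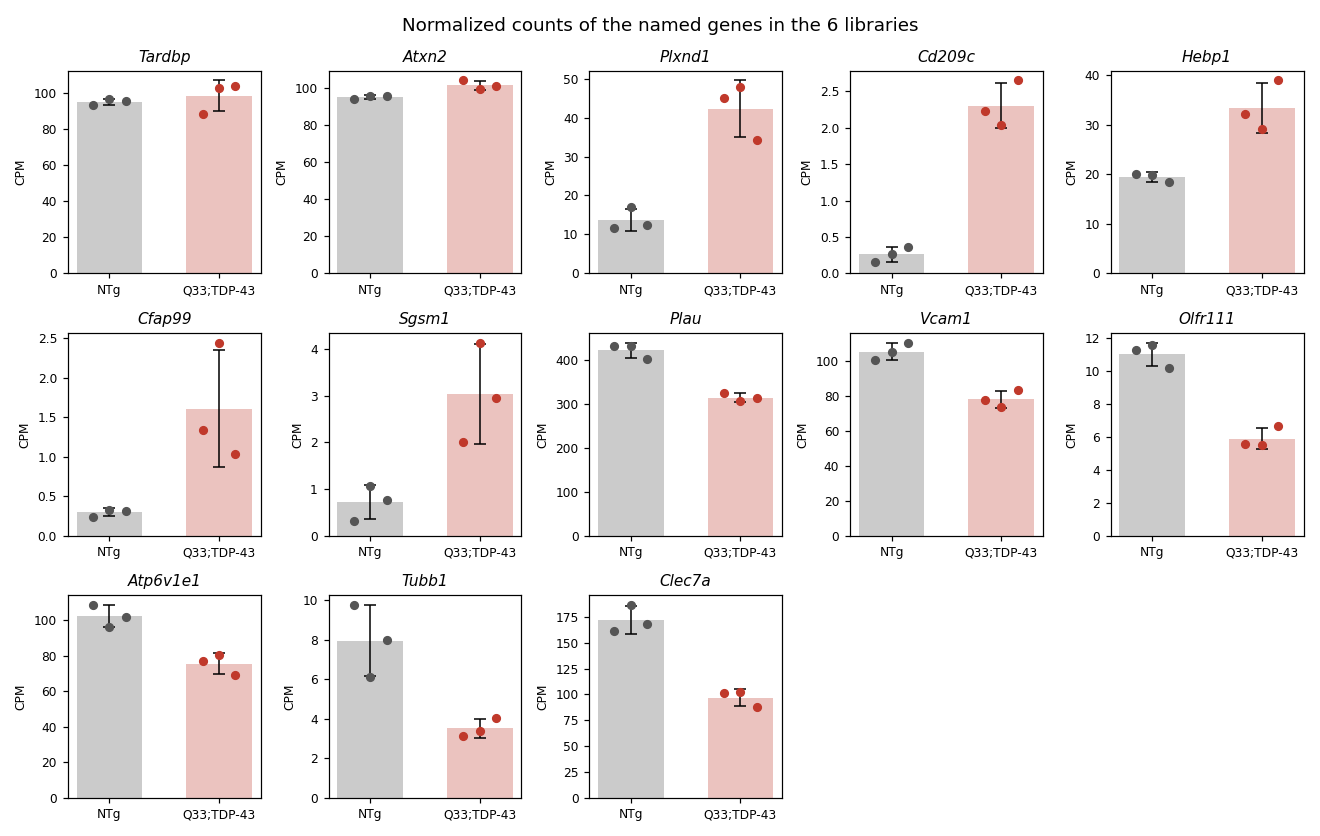
Normalized counts (CPM, linear axes from 0) of the 13 named genes in the 3 NTg (grey) and 3 ATXN2-Q33;TDP-43 (red) libraries, left to right in order of replicate number; bars are means, error bars are SD and points are libraries. Plxnd1 stands at 13.7 CPM in NTg and 42.3 CPM in the mutants, Clec7a at 172 and 96.9 CPM, and Tardbp at 95.0 and 98.4 CPM.

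By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 16248 genes passed an adjusted p of 0.05, 0 higher and 0 lower. An unadjusted p under 0.05 was reached by 368 genes (2.26%), 228 with a positive and 140 with a negative fold change. P-values without any difference would put a share of 0.05 of the genes there, more than was seen. A count of 0 therefore need not mean that no gene differs. DESeq2 called 7 genes, 5 higher (Plxnd1, Gm42653, Hebp1, Cd209c and Emp1) and 2 lower (Clec7a and Plau), with 398 at an unadjusted p under 0.05. Its adjusted p was 8.14e-11 for Plxnd1 and 3.84e-09 for Clec7a. The voom fit of limma called 0, with 285 at an unadjusted p under 0.05. Gm42653 and Emp1 are named after their values were seen. Libraries of the 2 groups did not overlap for 1113 genes (6.85%), where chance gives 10%. The 95% interval had a median half-width of 0.49 on the log2 scale, and 0.29 for the 8347 genes above 10 CPM. In data simulated with the real library sizes and gene dispersions (15880 genes), the test called 39.7% of genes changed 2-fold and 74.2% of those above 10 CPM. Genes were drawn independently there, without the structure that the real libraries share, so these shares may not hold for the real data. Smaller differences, or differences in low genes, were mostly not called in the simulation and may have been missed here. The alignments of NTg replicates 7 and 9 are named as combined and the others are not, a possible batch that holds NTg libraries only; fits that take it into account rest on NTg replicate 11 alone. With it as a covariate the log2 fold change of Plxnd1 was 1.76 and that of Clec7a -0.79, and 0 genes passed. With neighbouring sample codes (7 and 8, 9 and 10, 11 and 12) as a block, an alternative added after the data were seen, edgeR called 71 genes, 51 higher and 20 lower, with an adjusted p of 3.09e-06 for Plxnd1 and 3.26e-06 for Clec7a; the labels name no such pairs.

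Among lists of microglial genes, the disease-associated list, genes known to be induced in microglia around plaques and in degeneration, had 22 of 27 members with a negative fold change and a median log2 fold change of -0.13. None passed the test over all genes; 1 member, Clec7a, passed when adjusted over the list alone. Axl, a receptor for dying cells, had a log2 fold change of -0.28 (SE 0.10), and Ch25h, which makes 25-hydroxycholesterol, had -0.56 (SE 0.25). The set test camera with a preset correlation called the list lower (adjusted p = 7.52e-08), but the adjusted p was 0.734 with an estimated correlation. Inflammatory cytokines and NF-κB targets had 25 of 29 members with a negative fold change and a median of -0.14 (camera adjusted p = 3.86e-06; adjusted p = 0.751 with an estimated correlation). Tlr2, a receptor of bacterial lipoproteins, had a log2 fold change of -0.28 (SE 0.09), and the chemokines Ccl12 and Ccl4 had -0.32 (SE 0.12) and -0.28 (SE 0.11), none past the test. Lysosomal genes had 44 of 50 members with a negative fold change and a median of -0.08 (camera adjusted p = 4.15e-07; adjusted p = 0.846 with an estimated correlation), with Neu1, a sialidase, at -0.23 (SE 0.08) and the proton pump subunit Atp6v1b2 at -0.22 (SE 0.09). Without ATXN2-Q33;TDP-43 replicate 10 the median of the lysosomal list was -0.02 and its call ended, and the medians of the disease-associated and inflammatory lists were -0.06 each, still called. Among the 6 fits that left out 1 library, the lowest medians were -0.15 for the lysosomal list and -0.18 for each of the disease-associated and inflammatory lists.

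Homeostatic microglial genes were not called: 14 of 21 members had a negative fold change, with a median of -0.03 (camera adjusted p = 0.599). This depended on single libraries, in calls at the preset correlation of 0.01. The estimated correlation with all 6 libraries was 0.885 (camera adjusted p = 0.921 with it). At the preset value camera called the list higher without ATXN2-Q33;TDP-43 replicate 10 (median 0.10, adjusted p = 0.00755), and lower without replicate 12 (-0.16, adjusted p = 7.62e-05) or without NTg replicate 9 (-0.08, adjusted p = 0.0348). It was also called lower with the combined alignments as a covariate (-0.18, adjusted p = 4.18e-05). P2ry12, the purinergic receptor that marks resting microglia, measured 731 ± 70.3 CPM in NTg and 705 ± 119 CPM in the mutants (SD, n = 3 each). Tmem119 measured 517 ± 79.7 and 500.4 ± 127 CPM, and Cx3cr1, the fractalkine receptor, 1831 ± 150.3 and 1798 ± 303 CPM. Interferon-stimulated genes had 18 of 36 members positive and a median of -0.02, not called, but were called lower without NTg replicate 9 (median -0.09, adjusted p = 0.0466) and with the combined alignments as a covariate (-0.11, adjusted p = 0.00286). Cxcl10, a chemokine induced by interferon, had a log2 fold change of -0.48 (SE 0.16). Complement and Fc receptor genes had a median of -0.08, phagocytosis receptors -0.04, class I antigen presentation -0.05 and class II -0.03, none called. Complement genes were called lower without NTg replicate 9 (median -0.11) or ATXN2-Q33;TDP-43 replicate 8 (-0.10) or 12 (-0.16) and with the combined alignments as a covariate (-0.15, adjusted p = 0.00452). Class II was called lower without replicate 8 (-0.14) and phagocytosis receptors without replicate 12 (-0.08). Without ATXN2-Q33;TDP-43 replicate 10 the complement median was 0.04.

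The heat shock list had 15 of 15 members at a positive fold change and a median log2 fold change of 0.24. The near-identical chaperone genes Hspa1b and Hspa1a, whose reads cannot be fully told apart, had log2 fold changes of 0.65 (SE 0.21) and 0.57 (SE 0.19), and the endoplasmic reticulum chaperone Hspa5 had 0.29 (SE 0.13); none passed the test. Camera called the list higher (adjusted p = 3.71e-09), but the adjusted p was 0.751 with an estimated correlation, and the summed level of 9426 ± 1375 CPM in NTg and 11496 ± 1052 CPM in the mutants (SD, n = 3 each) had an exact two-sided permutation p of 0.2. With the combined alignments as a covariate, where NTg rests on 1 library, the heat shock median was 0.16 and the call ended (adjusted p = 0.0763). Immediate early genes, which tissue dissociation is known to induce, had 20 of 28 members positive and a median of 0.09, not called (camera adjusted p = 0.165), with Fosb at 0.27 (SE 0.12). They were called higher without NTg replicate 11 (median 0.19) or ATXN2-Q33;TDP-43 replicate 10 (median 0.17) and, with all 6 libraries, under a stricter filter (median 0.10, adjusted p = 0.0296). They were called lower with the combined alignments as a covariate (median -0.06, adjusted p = 0.0384). Ribosomal protein genes had 76 of 78 members with a negative fold change and a median of -0.11 (camera adjusted p = 8.34e-11; adjusted p = 0.846 with an estimated correlation). The mitochondrially encoded genes had 12 of 15 negative and a median of -0.11 (camera adjusted p = 0.0122; adjusted p = 0.846 with an estimated correlation), with mt-Nd1 at -0.21 (SE 0.09). The ribosomal call ended without ATXN2-Q33;TDP-43 replicate 10 (median -0.04), and the mitochondrial call ended in 4 of the 6 fits that left out 1 library, those without NTg replicate 9 or 11 or without ATXN2-Q33;TDP-43 replicate 10 or 12 (highest median -0.04).

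**Figure D2:**
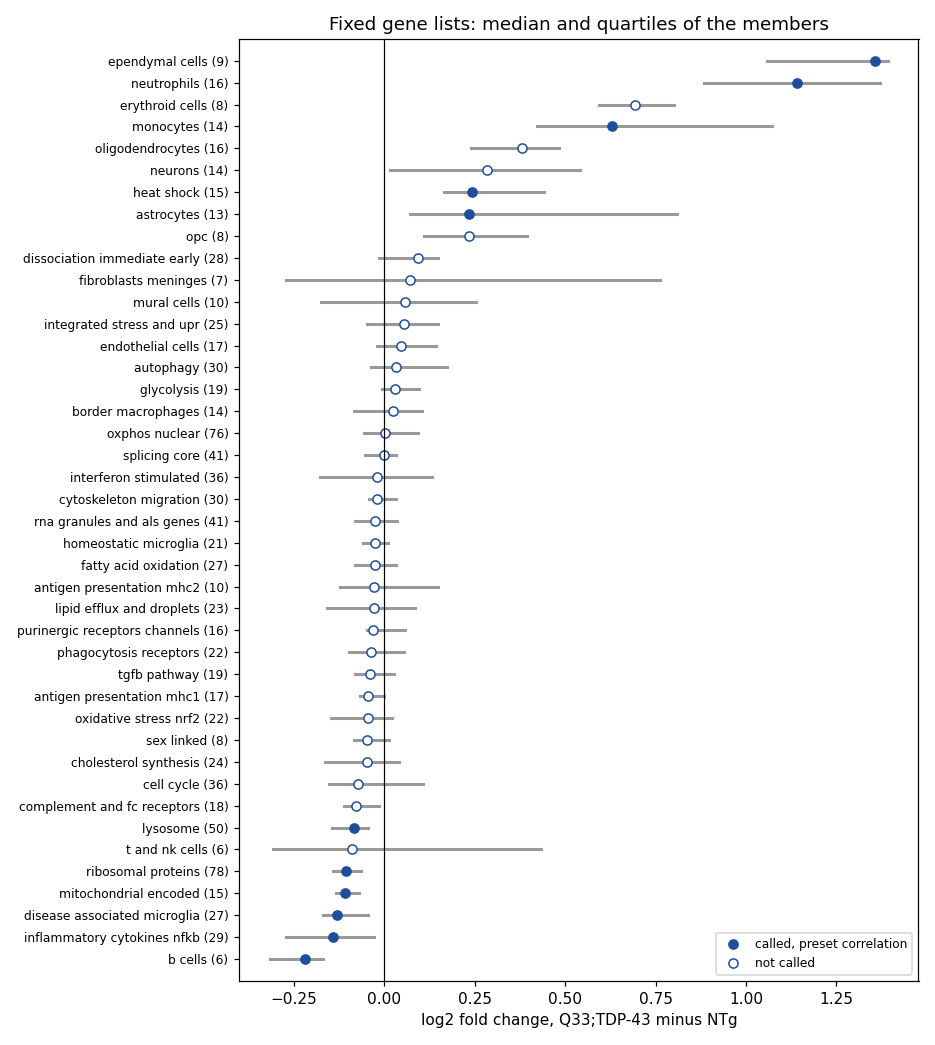
Median (point) and quartiles (line) of the members' log2 fold changes, ATXN2-Q33;TDP-43 minus NTg, for the 42 fixed lists, with the number of tested members in parentheses; filled points are lists called by camera with a preset correlation, open points are not called. Ependymal markers have the highest median, 1.36, and B cell markers the lowest, -0.22; with an estimated correlation 0 lists were called.

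Markers of cells other than microglia were present and uneven between libraries. All 9 tested ependymal markers, genes of the ciliated cells that line the central canal, had a positive fold change, with a median of 1.36; Rarres2 had 1.36 (SE 0.49), Ccdc153 1.39 (SE 0.56) and Foxj1, the transcription factor of motile cilia, 1.06 (SE 0.44), none past the test. Their summed level was 31.2, 55.5 and 33.5 CPM in NTg replicates 7, 9 and 11 and 41.7, 178 and 68.3 CPM in ATXN2-Q33;TDP-43 replicates 8, 10 and 12. Camera called the list higher (adjusted p = 2.40e-09; adjusted p = 0.751 with an estimated correlation), and the exact two-sided permutation p of the sum was 0.2. The ependymal median was 0.55 without ATXN2-Q33;TDP-43 replicate 10, still called. Neutrophil markers had 16 of 16 members positive and a median of 1.14, but their sums of 1041 ± 275 CPM in NTg and 1677 ± 948 CPM in the mutants (SD, n = 3 each; exact two-sided permutation p = 0.5) overlapped. S100a9, an abundant neutrophil protein, ran from 15.7 to 562 CPM within the mutants alone. Monocyte markers had 13 of 14 positive and a median of 0.63, astrocyte markers 11 of 13 and 0.23, and B cell markers 1 of 6 and -0.22. These 4 calls (camera adjusted p = 0.00284 for neutrophils, 0.00109 for monocytes, 0.0204 for astrocytes and 0.0210 for B cells; adjusted p = 0.846 with an estimated correlation for each) all ended in at least 3 of the 6 fits that left out 1 library. Monocytes and neutrophils lost their calls without NTg replicate 9 or ATXN2-Q33;TDP-43 replicate 8 or 10. Over the 6 fits their medians ran from 0.42 to 1.07 and from 0.43 to 1.70. Astrocytes lost theirs without NTg replicate 7 or 11 or ATXN2-Q33;TDP-43 replicate 10 (medians from -0.13 to 0.70 over the 6 fits). B cells lost theirs without NTg replicate 7 or 9 or ATXN2-Q33;TDP-43 replicate 10 or 12 (medians from -0.37 to -0.20 over the 6 fits). With the combined alignments as a covariate monocytes (0.53), astrocytes (0.43) and B cells (-0.10) were not called. Under it oligodendrocyte (1.98) and erythroid (1.70) markers were called higher.

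**Figure D3:**
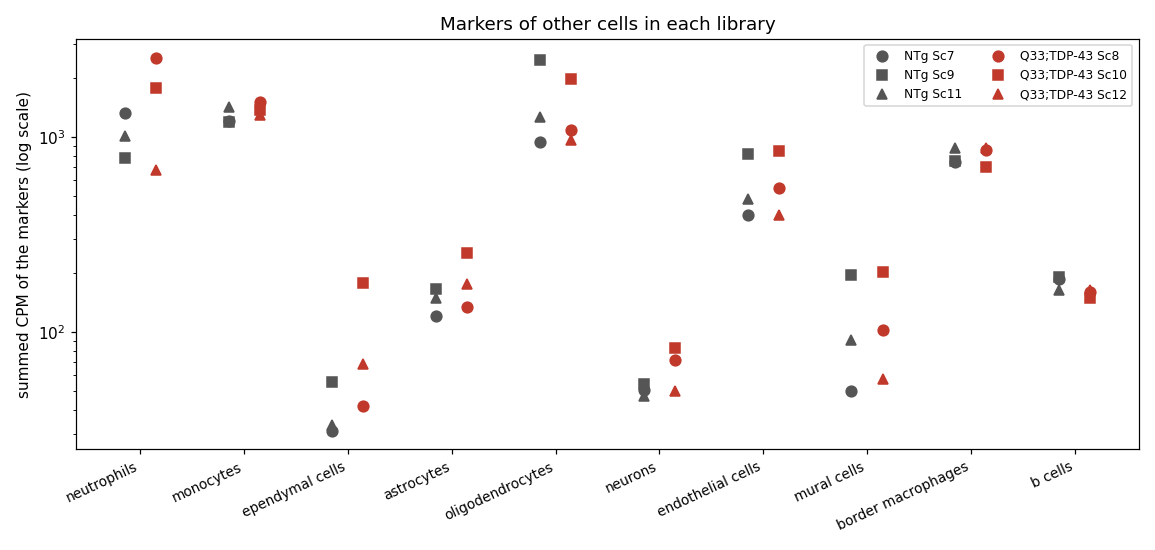
Summed CPM (log axis) of the markers of 10 other cell types in each library, NTg in grey and ATXN2-Q33;TDP-43 in red; circles are replicates 7 and 8, squares 9 and 10, and triangles 11 and 12. NTg replicate 9 and ATXN2-Q33;TDP-43 replicate 10 hold the most oligodendrocyte markers, 2489 and 1988 CPM, and replicate 10 the most ependymal markers, 178 CPM.

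Oligodendrocyte markers (median 0.38, sums from 942 to 2489 CPM) and endothelial markers (median 0.05, sums from 398 to 851 CPM) were not called, but single libraries set their direction. At camera's preset correlation both were called higher without NTg replicate 9 (medians 2.14 and 0.69, adjusted p = 5.04e-07 and 1.79e-05). Without ATXN2-Q33;TDP-43 replicate 10 both were called lower (medians -1.44 and -0.58, adjusted p = 0.00151 and 0.00601). The estimated correlations of these lists with all 6 libraries were 0.743 and 0.830 (camera adjusted p = 0.921 with them, for each). With the block of neighbouring codes camera called 13 lists at the preset correlation and 0 with an estimated one. The block added oligodendrocytes (higher, median 0.36, adjusted p = 0.0133), immediate early genes (higher, adjusted p = 0.0485) and complement genes (lower, adjusted p = 0.0478). Neutrophils lost their call (median 0.65, adjusted p = 0.0694). The summed oligodendrocyte level went the other way, 1568 ± 815 CPM in NTg and 1347 ± 558 CPM in the mutants (SD, n = 3 each). In the fit without the block 13 of 16 oligodendrocyte markers were positive, but Mbp had -1.24 (SE 1.02) and Mobp -1.34 (SE 1.28). In a principal component analysis the first component, with 45.2% of the variance, set ATXN2-Q33;TDP-43 replicate 10 (54.1) and NTg replicate 9 (25.9) apart from the other 4 libraries. Without these 2 libraries 1 gene passed, Plxnd1, and 6 lists were called. Xist, transcribed from the inactive X chromosome of females, measured 525 and 562 CPM in replicates 7 and 8 and from 953 to 1168 CPM in the others, while 4 Y-linked genes summed to 185 and 169 CPM in replicates 7 and 8 and from 68.9 to 89.6 CPM in the others. In all, camera called 11 of 42 lists, 5 higher and 6 lower, with the preset correlation, and 0 with an estimated correlation or with fry; fry's test for change in either direction called 1, the disease-associated list (adjusted p = 0.0299). That list without Clec7a had a median of -0.12 and an unadjusted p of 0.338 in the same test.

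Of the 31 lists not called, 15 were called when some single library was left out, 5 of these in both directions. The lists not described above had camera adjusted p-values from 0.0839, for neurons, to 0.790, for border macrophages. Neuronal markers had a median log2 fold change of 0.28, with Meg3, a long non-coding RNA, at 0.98 (SE 0.32), and erythroid markers 0.69. Without ATXN2-Q33;TDP-43 replicate 8 these medians were -0.17 and -0.30, and without replicate 12 they were 0.51 and 1.19, both called higher. Oligodendrocyte precursors had 0.23 (from -0.46 to 0.54 when single libraries were left out), mural cells 0.06 (from -0.44 to 0.90), meningeal fibroblasts 0.07 (from -0.23 to 0.47), border macrophages 0.02, and T and NK cells -0.09. Mural cells were called lower without NTg replicate 7 (-0.29) and higher without NTg replicate 9 (0.90). Fibroblasts were called higher without NTg replicate 9 (0.34) or ATXN2-Q33;TDP-43 replicate 12 (0.47), and precursors without replicate 12 (0.53). Among metabolic lists the medians were -0.05 for cholesterol synthesis (called lower without NTg replicate 11, -0.10), -0.03 for lipid efflux and droplets, -0.03 for fatty acid oxidation, 0.03 for glycolysis and 0.0026 for nuclear genes of oxidative phosphorylation (called lower with the combined alignments as a covariate, -0.13). Autophagy had 0.03, the integrated stress and unfolded protein responses 0.05, oxidative stress genes -0.05, cell cycle genes -0.07 and the TGF-β pathway -0.04. Cell cycle genes were called lower without NTg replicate 9 (median -0.18) or ATXN2-Q33;TDP-43 replicate 8 (-0.14) and with the combined alignments as a covariate (-0.40), and higher without NTg replicate 11 (0.12). RNA granule and amyotrophic lateral sclerosis genes had a median of -0.02, with Chchd10, a mitochondrial protein, at 1.20 (SE 0.45) and the axonal kinesin Kif5a at -0.96 (SE 0.46). Core splicing factors had -0.00062, cytoskeleton and migration genes -0.02, purinergic receptors and channels -0.03 and sex-linked genes -0.05.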

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

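The block, the ratio of Y-linked genes to Xist, the combined alignments and the fit without replicates 9 and 10 were chosen after seeing the data. By the labels, no paired analysis was possible because the groups share no replicate number. The block of neighbouring codes fitted instead pairs libraries by the numbers in their titles, which alternate between the genotypes. It was chosen after the data were seen, and the labels name no pairing. Against 0 genes called, DESeq2 called 7 (5 higher, 2 lower), edgeR without a filter 6 (5 higher, 1 lower) and with the first residual principal component as a covariate 2 (1 higher, 1 lower). Leaving out each library gave 0 to 2 genes, 0 to 2 higher and 0 lower; the 2, Thbs1 and Plxnd1, came without ATXN2-Q33;TDP-43 replicate 12. Without NTg replicate 9 and ATXN2-Q33;TDP-43 replicate 10, 1 gene passed (1 higher, 0 lower). A block of neighbouring codes gave 71 (51 higher, 20 lower). No other pairing of NTg with mutant libraries gave more than 2 genes as blocks. Whether the pools were prepared or composed in neighbouring pairs could not be decided. Tardbp (log2 0.01 to 0.12) and Atxn2 (0.07 to 0.12) kept their direction and stayed short of the threshold in all 23 alternatives, and the 11 other named genes kept their direction in all 22 or 23. Against 11 lists called, 0 were called with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, and 6 without replicates 9 and 10; leaving out each library gave 8 to 18, the 18 without ATXN2-Q33;TDP-43 replicate 12. Of the 11 called lists, 4 (disease-associated, inflammatory, heat shock and ependymal) kept call and direction whichever library was left out. Camera's direction turned for neutrophils without replicate 8 (median 0.43; 1.70 without replicate 12) and without replicates 9 and 10 (median 0.62), where the median stayed positive, and for astrocytes without replicate 10 (median -0.13; 0.70 without replicate 8). A change of direction is counted for called lists only; of 31 lists not called, 25 changed camera's direction in at least 1 alternative. Depth, spread and the number of libraries were not varied apart, so what depth alone limits is unknown.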

Other observations

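The block of neighbouring codes and the tests on chromosome 6, the ependymal markers and the pairings were chosen only after the results they follow were seen, except the test of the other genes of the chromosome 6 stretch and the splits of the libraries for genes and lists, which were set before their own results were known.

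With neighbouring sample codes (replicates 7 and 8, 9 and 10, 11 and 12) as a block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 71 genes where it called 0 without the block. Of the 51 that were higher, Cfap46 (log2 fold change 1.68, SE 0.18), Spag16 (1.86, SE 0.31), Hydin (1.42, SE 0.21), Rsph4a (1.35, SE 0.21) and Foxj1 (0.97, SE 0.19) are given as single genes; no list that holds all of them was fixed or tested. Among the fixed lists, 4 of 9 ependymal markers were called higher (Ccdc153, Hydin, Foxj1 and Rarres2; Fisher's exact test over all tested genes, adjusted p = 1.74e-06), and 3 of 28 immediate early genes (Fosb, Fos and Jun; adjusted p = 0.00509). Fisher's test takes members as independent, and in the fit without the block these lists had estimated correlations of 0.822 and 0.458. Camera with the block and an estimated correlation called 0 lists (adjusted p = 0.805 for both). The immediate early genes moved by small steps: Fos had a log2 fold change of 0.27 (SE 0.05) and Jun 0.22 (SE 0.04).

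The 20 genes that were lower under the block included Clec7a (log2 fold change -0.83, SE 0.06), Plau (-0.43, SE 0.05), Vcam1 (-0.43, SE 0.06), the collagen receptor Mrc2 (-0.60, SE 0.08), the matrix protease Mmp14 (-0.40, SE 0.08), the chemokine Ccl2 (-0.35, SE 0.07), the peptide endothelin-1 gene Edn1 (-0.51, SE 0.10) and the immune checkpoint receptor Pdcd1 (-0.85, SE 0.17). These genes are named after their values were seen. Of the fixed lists, the disease-associated and inflammatory lists each held 1 gene called lower under the block (Clec7a and Ccl2), which was no enrichment (adjusted p = 0.627 for each).

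Of the 47 genes at an unadjusted p under 0.01, 9 lay within 19.4 Mb of chromosome 6 (mm10, 115954811 to 135383173), a stretch drawn around these genes: Plxnd1, Lrrc23, Foxm1, Hebp1 and Emp1 with positive and Atp6v1e1, Clec1b, Clec1a and Clec7a with negative fold changes, and 4 of the 10 smallest p-values were among them. A permutation test that shuffled p-values over genes gave a 10 Mb bin with as many as the 6 seen there at p = 0.0002. This argues against chance placement of genes that vary independently. Shuffling takes genes as independent, but Clec1b, Clec1a and Clec7a of this bin lie close together (129397297 to 129472779) and share a direction. The p-values of such shuffles may therefore be too small. With markers of 4 other cell types as a covariate the members kept a median share of their fold of at least 0.987. Single members kept less: Lrrc23 kept 0.485 with ependymal and 0.656 with astrocyte markers, and Emp1 0.720 with neutrophil markers. With oligodendrocyte markers the lowest share was 0.966, for Hebp1. The bin still stood out with neutrophil (5 genes), astrocyte (4) and oligodendrocyte (10) markers (largest permutation p = 0.0458). It did not with ependymal markers (3 of 132 genes at p under 0.01), which leaves carried-over cells open. A bin with 6 or more such genes appeared in 4 of the 10 splits of the 6 libraries, the genotype split among them, the highest other count being 12. The 10 splits are too few for a share under 0.05. The splits with 12 had 149, 762 and 781 genes at p under 0.01, and the bin of the split with 149 lay on chromosome 18. Each of them kept libraries of neighbouring codes on the same side, and such libraries deviated together. Their counts may come from that structure and do not show how often groupings like the genotype's reach 6. The other splits that parted all neighbouring codes, as the genotype split did, had 3, 1 and 1 such genes in their highest bin. They are too few to decide. A candidate explanation is strain-specific DNA around an engineered locus: the Gt(ROSA)26Sor locus, often used for knock-ins, lies 2.88 Mb from Plxnd1, but the labels give no insertion site, and of the other 173 tested genes of the stretch 4.05% had p from 0.01 to 0.05 against 1.96% elsewhere (odds ratio 2.11, 95% interval 0.829 to 4.50, Fisher's exact p = 0.0878), which leaves it open. An effect of the genotype on each of these genes stays open too and was not tested apart from it.

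Ependymal markers had positive fold changes in 9 of 9 members, and the sums of each mutant library over the NTg library of the neighbouring code were 1.33, 3.21 and 2.04. Uneven carry-over of ependymal cells past the CD11b beads may account for this. The estimated correlation between members within genotypes was 0.822, so the markers also moved together between libraries of one genotype. That does not single out carry-over, since the lists ran from -0.12 (sex-linked genes) to 0.885 (homeostatic microglial genes), with neutrophil markers at 0.872. None of the 9 is in another fixed list, and their mean NTg levels were 0.687 to 7.52 CPM. A lower share of microglia in the mutant libraries would raise markers of every other cell alike, and the log2 ratio of ependymal to oligodendrocyte sums differed by 1.22 (SE 0.40) and to endothelial sums by 0.96 (SE 0.45). Without Trf, which is abundant here, the first became 1.33 (SE 0.87), and without Slc2a1 the second 0.96 (SE 0.47), so this explanation and the first cannot be told apart with 3 pools a group. A change in the ependymal cells of the mutants stays open and was not tested.

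Libraries with neighbouring codes deviated together from their group means, with correlations across genes of 0.25, 0.60 and 0.39. Of the 6 ways to pair NTg with mutant libraries, 1, the neighbouring one, had a mean correlation as high as 0.412; the next had 0.255, and as blocks they gave 71 and 2 genes. Pools prepared or composed in neighbouring pairs could produce this, and the Xist and Y-linked levels of replicates 7 and 8 fit such pairs, but the labels name no pairing, and 6 pairings are too few to decide.

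Among the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, all 10 gave at least the 0 genes of the genotype split, which a count of 0 fixes beforehand, the highest other being 3, and 8 gave at least its 11 lists, the highest other being 22. Splits that kept libraries of neighbouring codes on the same side had from 108 to 781 genes at p under 0.01. Splits that parted all neighbouring codes had from 6 to 47, the 47 being the genotype split. This points to a structure of the samples that goes with the neighbouring codes. Besides the genotype split, those that parted all neighbouring codes gave 16, 4 and 15 lists.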
